A study of Mus musculus with 6 samples.

How the data were processed

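RNA of 6 samples of LX-2 cells was hybridised to Affymetrix whole-transcript arrays, 3 with antimiR-214 and 3 with the control inhibitor, grouped by sample title and source name. Total RNA was labelled with biotin after fragmentation, per the labels' protocols. The extraction protocol names both frozen liver and cultured cells, and only the cell line is analysed here. The deposited values are log2 probe set intensities made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes, with versions not given in the sources used here. The base of the deposited log2 values follows from RMA, as no header states it. Values of 33297 probe sets lay between 1.36 and 14.2, none was missing, and no arrays were identical. No scanner files or detection calls were used here, so signal over background is unknown.

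Probe sets were named through the array's probe table. It paired 19460 probe sets with 1 gene symbol and 1754 with several, and 12083 were not in it. Genes were named only from probe sets with 1 symbol, and for the 769 genes with over 1 probe set the brightest over all 6 arrays was used, giving 18417 genes. No further normalization or filter was applied. DNM3OS, which the naming rule includes if measured, had no probe set with a single symbol and was not analysed here as a gene. Some items of the fixed lists are not reported here. The reference gene table is of the mouse assembly GRCm38.p6 and was used only to recognise coding symbols.

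Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The lists, tests, alternatives and naming rule were fixed before the data were examined. The 20 lists were the miR-214 locus, published miR-214 targets, stellate activation and matrix, TGF-β response, EGFR/MAPK output, stellate quiescence, cell cycle, interferon response, unfolded protein and integrated stress response, cholesterol synthesis, NF-kB cytokines, p53 targets, hypoxia and glycolysis, hedgehog, Wnt and beta-catenin, YAP targets, and markers of hepatocytes, endothelium, macrophages and leukocytes, and cholangiocytes and epithelium. Of 503 list genes, 470 were measured. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 19 lists, and with camera at an estimated correlation and fry as alternatives. Some genes are in over 1 list, such as CCN2, TGFB2, CCND1 and HHIP.

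The named genes were up to 12 higher and 12 lower genes past the threshold with the largest fold and no overlap between groups, up to 4 members per list with the smallest p, and a fixed set of stellate and miR-214 genes. Olfactory receptor, pseudogene, uncharacterised and small RNA symbols were to be skipped among the first, and 0 were. A symbol was read as a pseudogene where another measured symbol is followed by P and a number. This reading was narrowed after the data were seen, because the first version took MMP1, a coding gene, for a pseudogene. Members of lists beyond these are named as examples and were chosen after their values were seen.

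The alternatives were median centring, quantile normalization, filters at the 50th and 25th percentiles of mean intensity, the mean of a gene's probe sets, all probe sets, an intensity trend or a robust variance prior, array weights, the replicate number as a block, an adjusted p of 0.1, and leaving out each of the 6 arrays. Data of 18417 genes were simulated with the spread of these arrays, with 50 genes changed at each fold. Limma called 0%, 10%, 66% and 96% of those changed 1.2-fold, 1.3-fold, 1.5-fold and 2-fold, with 4 false calls. Far fewer genes were changed there than passed in the real data (2636). This makes the adjusted threshold stricter, so these shares may understate the recovery of small changes here. The simulated spread was also drawn without regard to brightness. In the real data the median SD was 0.15 log2 units in the dimmest decile of genes and 0.063 in the brightest. The shares are thus averages and do not hold for dim or bright genes alone. Camera at an unadjusted p under 0.05 called 4 of 200 unchanged lists of 30 genes and 50 of 50 lists moved by 0.3 log2 units. The simulated genes were drawn independently, so these rates do not cover lists of correlated genes. The interferon list, for 1, had an estimated correlation of 0.25. A planned test of miR-214 seed sites in 3′ untranslated regions was not run, since no human genome was used here.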

Results

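Gene expression was measured on 6 Affymetrix arrays in LX-2 cells, an immortalised line of human hepatic stellate cells, the liver cells that lay down scar matrix when activated. The cells had been transfected with 10 nM of a locked nucleic acid inhibitor of the microRNA miR-214 (antimiR-214, 3 arrays) or of a control inhibitor (3 arrays). All cells were then deprived of serum for 9 h and given 3 ng/mL TGF-β1, a cytokine that activates stellate cells, for 24 h. The organism field of the labels reads mouse, whereas the growth protocol calls the cells human and the array's probe table carries human gene symbols, so the values are treated as human. The comparison asks which transcripts differ when miR-214 is inhibited in TGF-β1-treated stellate cells. The array medians lay between 5.95 and 6.02 log2 units. Correlations over all 33297 probe sets were 0.990 to 0.992 within the antimiR-214 arrays and 0.993 to 0.995 within the control arrays. Between groups they were 0.987 to 0.989. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision.

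Among genes that rose with antimiR-214, IFIT2 (probe set 7929047), which encodes an interferon-induced antiviral protein, had the largest fold by the naming rule, from 5.15 ± 0.16 to 7.25 ± 0.19 log2 units (SD, n = 3), a 4.31-fold difference with limma adjusted p = 0.000113. ESM1, an endothelial proteoglycan, was 3.74-fold higher, and TFPI2, a protease inhibitor, was 2.96-fold higher. PMAIP1, a pro-apoptotic BH3-only protein, was 2.95-fold higher. IFI44, DUSP6, IFIT3 and SPRY4 were 2.78-fold, 2.77-fold, 2.61-fold and 2.53-fold higher. KITLG, MMP1, STC1 and IL6, which encode stem cell factor, interstitial collagenase, stanniocalcin and interleukin-6, were 2.49-fold, 2.44-fold, 2.41-fold and 2.40-fold higher. These 12 genes had adjusted p values of 0.000109 to 0.00137.

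The genes that fell most were of mixed function. FLACC1 (probe set 8058203) went from 6.69 ± 0.14 to 4.55 ± 0.22 log2 units (SD, n = 3), a 4.39-fold lower level with limma adjusted p = 0.000115. STPG4 was 4.38-fold lower, PYGM, the muscle glycogen phosphorylase, 3.89-fold lower, and CDKL4 3.78-fold lower. CD226, an adhesion receptor of lymphocytes, was 3.74-fold lower. CCDC62, APRG1, GCNA and NAIP were 3.41-fold, 3.38-fold, 3.25-fold and 3.12-fold lower, and MARVELD2, PLAC8L1 and ADAM32 were 3.11-fold, 3.07-fold and 3.01-fold lower. CDKL4 and MARVELD2 had means of 3.51 and 3.75 log2 units with antimiR-214, below the 3.77 under which the means of the dimmest 10% of genes lay.

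Of 18417 genes tested, 2636 (14.3%) passed an adjusted p of 0.05, 1263 higher and 1373 lower with antimiR-214. Which direction held more genes depended on the setting: 1486 were higher and 1132 lower with median centring, and 1852 were higher and 1455 lower among genes at or above the median intensity. Most differences were small: 461 of these genes differed by at least 1.5-fold (162 higher, 299 lower) and 69 by at least 2-fold (26 higher, 43 lower). The second count, of genes at 1.5-fold with an unadjusted p under 0.05, was 475, with 169 higher and 306 lower, against 214 higher and 262 lower with median centring. The groups did not overlap for 34.4% of genes, where chance gives 10%. The number past the threshold fell to 1727 without antimiR-214 replicate 2, and to 1319, 1385 and 1275 without control replicates 1, 2 and 3.

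**Figure D1:**
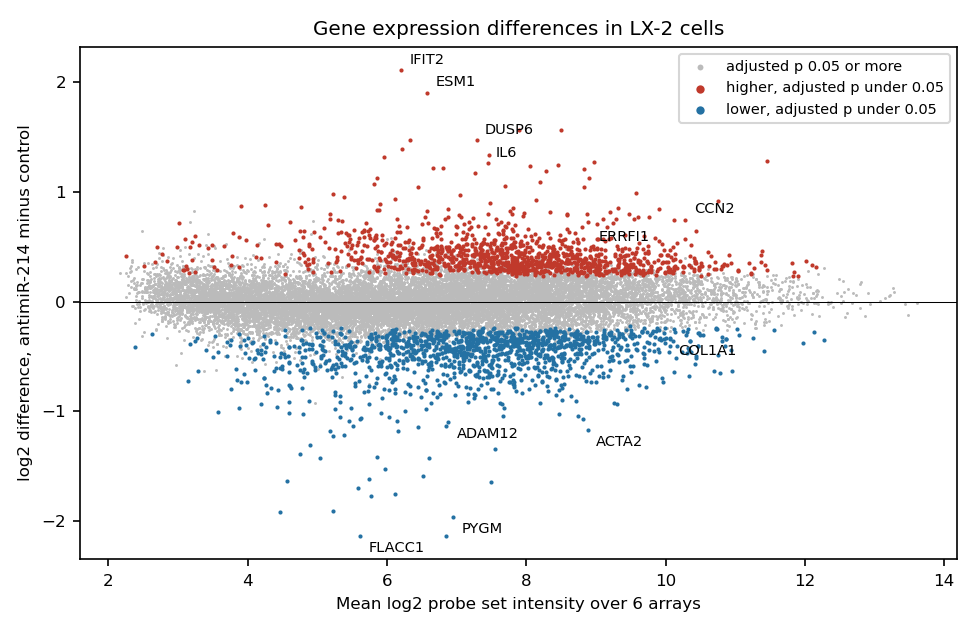
Each point is 1 of 18417 genes, with the mean log2 intensity over the 6 arrays on the x axis and the log2 difference between antimiR-214 and control on the y axis. Red and blue points are the 1263 higher and 1373 lower genes past an adjusted p of 0.05, with IFIT2 at 2.11 and FLACC1 at -2.13 at the ends of the range.

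A part of the feedback and output genes of EGFR and MAP kinase signalling rose. Of 31 measured members of this list, 16 rose and 1, EGFR, fell, 14 did not pass, and adjusted over the list alone 18 rose and 1 fell. The largest rises were in the MAP kinase phosphatase DUSP6 (1.47 ± 0.11 log2 units, SE) and in SPRY4 (1.34 ± 0.09), a Sprouty inhibitor of receptor tyrosine kinase signalling. DUSP1 and SPRY2 rose by 0.84 ± 0.07 and 0.82 ± 0.07. The ETS factors ETV1, ETV5 and ETV4 rose by 0.83, 0.72 and 0.71. The immediate-early genes EGR1 and FOS did not pass, at -0.09 and 0.19. The median of the list was 0.30 and its mean 0.42 log2 units, and the list mean lay between 0.37 and 0.46 on the antimiR-214 arrays against -0.05 to 0.03 on the control arrays. Camera called the list higher (adjusted p = 7.94e-10). With the gene correlation estimated from the data, and the fewer degrees of freedom of that form, camera did not call it (adjusted p = 0.253).

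ERRFI1 (probe set 7912157), which encodes MIG-6, an inhibitor of EGFR and a published target of miR-214, rose from 8.67 ± 0.10 to 9.17 ± 0.11 log2 units (SD, n = 3). This was a 1.41-fold difference with limma adjusted p = 0.00773, and it passed in every alternative tested (adjusted p 0.000186 to 0.0364). EGFR itself was lower by 0.27 ± 0.08 log2 units (SE) at an adjusted p of 0.0497, a call lost in 10 alternatives, among them leaving out any antimiR-214 array or control replicate 1 or 2 (adjusted p 0.00937 to 0.157 over all alternatives).

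A part of the cytokine and chemokine genes that respond to NF-kB rose. Of 27 measured, 10 rose, none fell and 17 did not pass, and adjusted over the list alone 10 rose and 1 fell. TNFAIP3, an inhibitor of NF-kB signalling, rose by 1.24 ± 0.07 log2 units (SE), IL6 by 1.26 ± 0.08, IL1B by 1.13 ± 0.07 and CXCL8 by 1.05 ± 0.08. TNF, PTGS2 and CSF3 did not pass, at -0.03, -0.01 and 0.00. The list passed in camera (adjusted p = 2.98e-05) and did not with an estimated correlation (adjusted p = 0.121 with an estimated correlation). The estimate was -0.01 here, below the preset 0.01, so correlation among the members does not account for the lost call. The fewer degrees of freedom that come with an estimated correlation do.

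A part of the interferon-induced genes rose. Of 40 measured, 11 rose and 1, DHX58, fell, and adjusted over the list alone 11 rose and 2 fell. IFIT2, IFI44 and IFIT3 rose by 2.11 ± 0.12, 1.47 ± 0.16 and 1.39 ± 0.11 log2 units (SE), and OASL rose by 0.93 ± 0.07. Other interferon-induced genes did not pass: ISG15 differed by 0.03, IRF7 by 0.02, MX1 by -0.16 and IFI44L by -0.82. The mean of the list on control replicate 1 was 0.18 log2 units above the control mean, against 0.19 to 0.24 on the antimiR-214 arrays and -0.04 and -0.13 on control replicates 2 and 3. Camera called the list higher (adjusted p = 0.0166; adjusted p = 0.630 with an estimated correlation). The call was lost without control replicate 3 (adjusted p = 0.0554), with fry (adjusted p = 0.0721) and among genes at or above the median intensity (adjusted p = 0.281), in a range of 0.000230 to 0.630 over all alternatives.

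Genes of stellate cell activation and matrix were on balance lower. Of 36 measured, 10 fell and 2 rose, and adjusted over the list alone 13 fell and 5 rose. ACTA2 (probe set 7934906), the smooth muscle actin that marks activated stellate cells, fell from 9.47 ± 0.07 to 8.30 ± 0.09 log2 units (SD, n = 3), a 2.25-fold lower level with limma adjusted p = 0.000197. COL3A1, COL5A1 and COL1A2 were 1.74-fold, 1.49-fold and 1.40-fold lower, and PDGFRB, a receptor for platelet-derived growth factor, was 1.35-fold lower. COL1A1 was 1.26-fold lower (adjusted p = 0.0223). MMP14, a membrane-bound matrix metalloproteinase, rose 1.53-fold and TIMP1, an inhibitor of metalloproteinases, rose 1.37-fold. Fibronectin (FN1) and DCN did not pass, at -0.02 and 0.00 log2 units.

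The matrix list was called lower by camera (adjusted p = 0.0398, and 0.566 with an estimated correlation). This call was lost without antimiR-214 replicate 2 (0.0697), control replicate 2 (0.0543) or control replicate 3 (0.0511), and with the replicate number as a block. The COL1A1 call was lost in 5 alternatives, among them leaving out antimiR-214 replicate 1 or any control array (adjusted p 0.000977 to 0.0850), the PDGFRB call without control replicate 1 or 2 (0.00153 to 0.0589), and the TIMP1 call without control replicate 3 (0.000235 to 0.0567).

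Genes of the TGF-β response went both ways. Of 37 measured, 5 rose and 6 fell, and adjusted over the list alone 11 rose and 7 fell. CCN2, a matricellular growth factor, rose by 0.75 ± 0.08 log2 units (SE). ADAM12 fell by 1.09 ± 0.09, TGFB2 fell by 0.65 ± 0.07 and SMAD3, a signal transducer of the TGF-β receptor, fell by 0.43 ± 0.07. TGFBR1 differed by 0.24 ± 0.07 and did not pass (adjusted p = 0.0664). Camera did not call the list (adjusted p = 0.635).

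**Figure D2:**
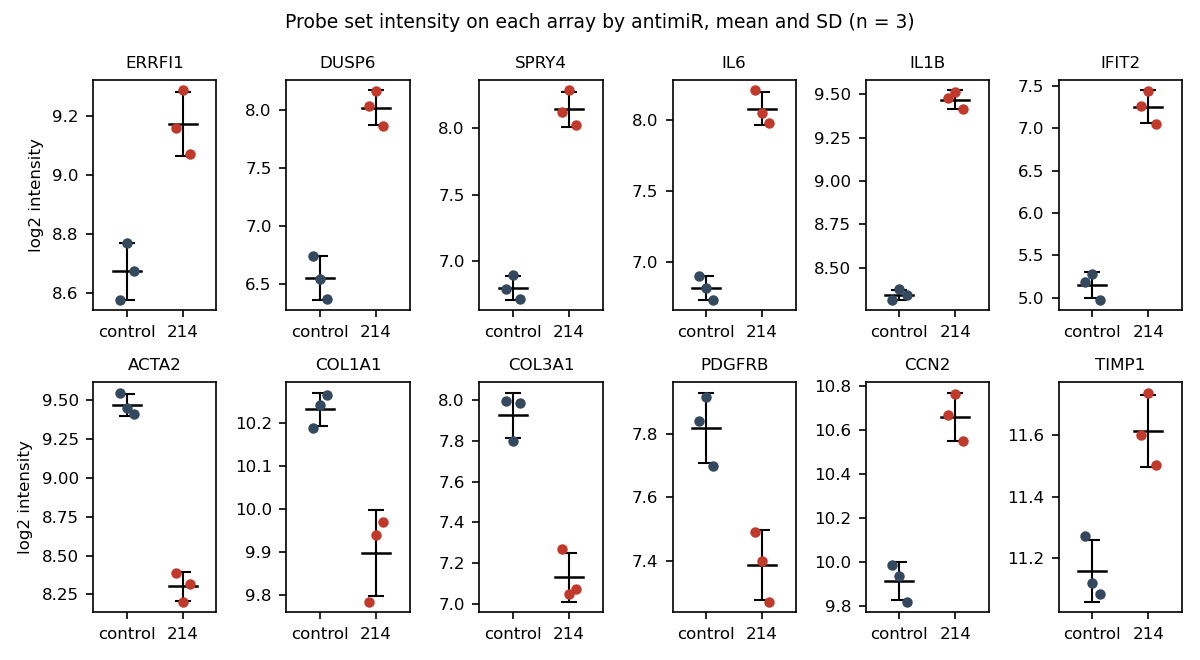
Each panel shows the log2 probe set intensity of a gene on the 3 control arrays (dark) and the 3 antimiR-214 arrays (red), with the mean and SD as bars, and each y axis has its own range. ACTA2, COL1A1, COL3A1 and PDGFRB are lower and the other genes higher with antimiR-214, and no gene's groups overlap.

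Published targets of miR-214 did not move together. Of 32 measured, 5 rose and 4 fell, and adjusted over the list alone 6 rose and 5 fell. BCL2L11, which encodes the pro-apoptotic protein BIM, rose by 0.68 ± 0.08 log2 units (SE), ERRFI1 by 0.50 ± 0.09 and JAG1, a Notch ligand, by 0.49 ± 0.08. EZH2, a histone methyltransferase, fell by 0.59 ± 0.07 and MAPK8 fell by 0.48 ± 0.07. The median of the list was -0.03, and camera did not call it (adjusted p = 0.806). The list named for the locus of the microRNA held 2 measured genes, DNM3 and TWIST1, and had no set test. TWIST1, which does not lie at the locus itself, rose by 0.30 ± 0.08 (limma adjusted p = 0.0466). This call was lost in 7 alternatives, among them leaving out antimiR-214 replicate 1 or 3 or any control array (adjusted p 0.00848 to 0.142). DNM3 differed by -0.23 ± 0.12 and did not pass.

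Camera did not call the lists of stellate quiescence, hedgehog, Wnt and YAP genes. Of 19 quiescence genes, 4 rose and none fell, also adjusted over the list alone (list adjusted p = 0.127). They were HHIP (0.86 ± 0.13 log2 units, SE), an inhibitor of hedgehog ligands, RELN (0.61 ± 0.08), PLIN2 (0.55 ± 0.08), a lipid droplet protein, and LHX2 (0.48 ± 0.08). Of 13 hedgehog genes, 1 rose and 2 fell, and adjusted over the list alone 1 rose and 3 fell (list adjusted p = 0.635). GLI2 and GLI3 fell by 0.32 and 0.32, calls lost in 6 and 8 alternatives, among them leaving out antimiR-214 replicate 1 or 2 or control replicate 1 or 2 (adjusted p up to 0.110 and 0.155), and SUFU differed by -0.20 and did not pass. Of 29 Wnt genes, 5 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.405). SFRP1, FZD8 and the cyclin CCND1 rose by 0.57, 0.50 and 0.64, and TCF7L1 fell by 0.46, a call lost without control replicate 1 or 3 (adjusted p 0.00143 to 0.0587). Of 23 YAP targets, 4 rose and 7 fell, also adjusted over the list alone (list adjusted p = 0.352). CCN2 rose while MYOF fell by 0.64 and RBMS3 fell by 0.74. The YAP list had a median of 0.01, a mean of -0.08 and a test direction of lower.

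Stress, hypoxia, p53 and cell cycle lists were called higher at adjusted p values near the threshold, and cholesterol synthesis lower. Of 29 hypoxia and glycolysis genes, 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0348; adjusted p = 0.608 with an estimated correlation). ENO2, PFKFB3 and NDRG1 rose by 0.43, 0.42 and 0.41 log2 units and the aldolase ALDOC fell by 0.50. Of 28 genes of the unfolded protein and integrated stress response, 4 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.0400; adjusted p = 0.608 with an estimated correlation). ATF3, PPP1R15A and DDIT3 rose by 0.66, 0.54 and 0.44, and the cystine transporter SLC7A11 fell by 0.78. Of 22 p53 targets, 6 rose and 2 fell, and adjusted over the list alone 9 rose and 2 fell (adjusted p = 0.0400; adjusted p = 0.608 with an estimated correlation). PMAIP1 rose by 1.56, PLK3 by 0.56 and CCNG1 by 0.39, and DDB2 fell by 0.38.

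Of 40 cell cycle genes, 5 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell (adjusted p = 0.0400; adjusted p = 0.630 with an estimated correlation). CCNE2, AURKB and NUF2 rose by 0.41, 0.39 and 0.31 log2 units and MCM5 fell by 0.33. Among 10000 brightness-matched random lists, the cell cycle list lay at percentile 75.9 by its median and 86.6 by its mean, within the central 95%. Of 21 cholesterol synthesis genes, none rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0400; adjusted p = 0.566 with an estimated correlation). MVK, FADS2 and LSS fell by 0.36, 0.34 and 0.34, and ACAT2 differed by -0.24 and did not pass. By their medians the stress response, hypoxia and cholesterol lists lay within it too, at 92.2, 90.1 and 5.01. By its mean the stress response lay within it, at 97.0, hypoxia on its upper bound and cholesterol outside it, at 1.05. The p53 list lay outside it by its median, at 97.8, and by its mean, at 99.9. The calls of these 5 lists and of the cholangiocyte list were lost without antimiR-214 replicate 2 (adjusted p 0.0697 to 0.135). They were also lost without control replicate 3 (0.0554 to 0.0867). Leaving out control replicate 1 also lost the cell cycle, stress response, hypoxia and cholesterol calls, and control replicate 2 the p53 and cholesterol calls. Without antimiR-214 replicate 1 the cell cycle and p53 calls were lost, and without replicate 3 the cholesterol and cholangiocyte calls. Of the 6 fits with 1 array left out, cholesterol kept its call in 1, and cell cycle and p53 in 2. Stress response, hypoxia and cholangiocyte markers kept theirs in 3. The calls of MCM5, AURKB, CCNE2, NUF2, FADS2 and LSS were each lost when 1 or more single arrays were left out (highest adjusted p 0.0523 to 0.109). Over all genes 14.3% passed in either direction, so the shares of members past the threshold in the cell cycle and cholesterol lists were near that of all genes.

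Markers of other liver cell types were measured beside these groups. Over all genes 14.3% passed in either direction, and the shares among the cholangiocyte and endothelial markers were near that. Of 12 cholangiocyte and epithelial markers, 2 rose and none fell, and adjusted over the list alone 4 rose (adjusted p = 0.0400; adjusted p = 0.566 with an estimated correlation). SOX9, a transcription factor, rose by 0.53 ± 0.09 log2 units (SE) and EPCAM by 0.56 ± 0.15, from a control mean of 3.70, a call lost in 8 alternatives, among them leaving out antimiR-214 replicate 2 or 3 or any control array (adjusted p 0.00830 to 0.211). SPP1 and KRT8 differed by 0.57 and 0.23 and did not pass. Of 14 endothelial markers, FLT1 and TIE1 rose by 0.54 and 0.36 and none fell, and adjusted over the list alone 3 rose (list adjusted p = 0.635, with a median of -0.03, a mean of 0.07 and a test direction of higher). TIE1 lost its call in 6 alternatives, among them leaving out antimiR-214 replicate 2 or 3 or control replicate 2 or 3 (adjusted p 0.00342 to 0.101). Of 16 macrophage and leukocyte markers, CD68 rose by 0.48 ± 0.09 and none fell, also adjusted over the list alone (list adjusted p = 0.806). None of 17 hepatocyte markers passed over all genes or adjusted over the list alone (list adjusted p = 0.431), with CYP2E1 at -0.24, APOA2 at -0.15, CYP3A4 at 0.14 and FGA at -0.10.

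**Figure D3:**
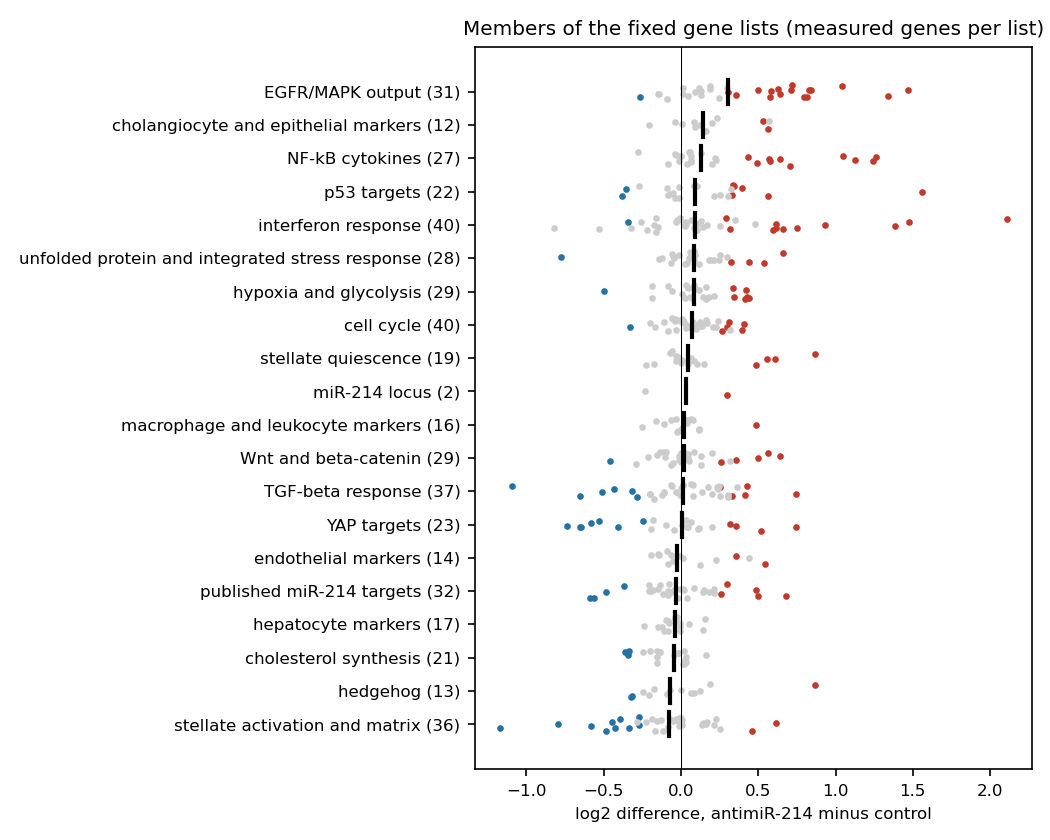
Each point is a measured member of 1 of 20 gene lists, placed by its log2 difference between antimiR-214 and control on the x axis, with the list median as a black bar and the number of measured genes in brackets. Red and blue points passed an adjusted p of 0.05 over all genes, and the EGFR/MAPK list has the highest median (0.30) and the matrix list the lowest (-0.08).

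Camera called 10 of 19 lists with a preset correlation, 8 higher and 2 lower. With an estimated correlation it called 0, with 2 lists, EGFR/MAPK and NF-kB, at an unadjusted p under 0.05. The fewer degrees of freedom of that form also bear on this, so the count does not measure gene correlation alone. Fry, which asks whether the genes of a list move on balance one way, called 5, and its mixed test, which asks for changes in either direction, called 18. The mixed test does not compare a list with other genes. As 14.3% of all genes passed the threshold, most lists would be called, so the 18 calls do not set these lists apart.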

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

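The tests weighed in this part were chosen after the results were seen. Probe sets that name no single gene were left out of the comparison, and some of them differed between the groups. Those with several symbols and those outside the probe table were each fitted and adjusted on their own. Their counts and adjusted p values are therefore not on the same scale as those of the genes. Of 1754 probe sets paired with several symbols, 115 were higher and 272 lower with antimiR-214 at an adjusted p under 0.05. Of 12083 probe sets outside the probe table, 2 were higher and 6 lower, and 1543 had an unadjusted p under 0.05. The probe set shared by DNM3OS and MIR214 differed by -0.24 ± 0.12 log2 units (SE, adjusted p = 0.204) and the one shared by DNM3OS and MIR199A2 by 0.06 ± 0.14 (adjusted p = 0.798).

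The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every other split mixes antimiR-214 and control arrays, so the difference between the groups adds to its spread. Low gene counts there were favoured in advance and are no null level. The real split gave 2636 genes past the threshold, where the highest of the other splits gave 0, and only the real split (1 of 10) gave as many. It gave 475 genes at 1.5-fold and an unadjusted p under 0.05 against at most 14, and 10 lists against at most 5, again 1 of 10 splits each.

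The rise of the EGFR/MAPK list was set against 3 technical explanations. An offset between the groups that depends on brightness is argued against, since the list mean lay at percentile 100 of 10000 brightness-matched random lists. A single array is argued against by the highest camera p with 1 array left out, 1.51e-09. An axis between the arrays that is unrelated to the groups is argued against. No split of the group-centred arrays gave a mean difference above 0.065, where the groups differed by 0.42. Centring removes any batch or handling difference that coincides with the groups, so such a difference was not tested and stays open. That the list follows miR-214 inhibition is a hypothesis and stays open beside an effect of the inhibitor's sequence on other transcripts, which 1 inhibitor and 1 control do not separate, and beside the loss of the call with an estimated correlation (adjusted p = 0.253).

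ERRFI1 is both a published miR-214 target and a member of the EGFR/MAPK list. Relief of published targets as a set cannot be decided. Without ERRFI1 the 31 other targets went both ways, with 13 above 0 and a median of -0.05. Limma's camera gave them a p of 0.570. A rise together with other EGFR/MAPK genes cannot be decided either. The list without ERRFI1 had a camera p of 1.48e-10, but leaving 1 of 31 genes out of a called list could hardly turn its call. The seed sites that bear on the first explanation were not tested.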

How the results depend on the processing

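No result changed direction past its threshold. Of 99 named genes, 84 passed, 68 of them in all alternatives that tested them; 74 of 1642 gene values lost and 31 gained a call. Leaving out 1 array gave 1275 (without control replicate 3) to 2556 genes past the threshold, 489 to 1316 higher and 726 to 1240 lower, and 2 to 8 lists. Single-array adjusted p ranges were 0.0314 to 0.0697 for matrix, 0.0136 to 0.163 for cell cycle, 0.000230 to 0.0554 for interferon, 0.0314 to 0.135 for the stress response, 0.0430 to 0.0872 for cholesterol, 0.0347 to 0.0884 for p53, 0.0124 to 0.0697 for hypoxia, 0.0150 to 0.0867 for cholangiocyte markers, 0.303 to 0.991 for hedgehog and 0.523 to 0.966 for macrophage markers; fewer arrays were used in each. An intensity trend gave 1996 higher genes and an adjusted p of 0.1 gave 1986.

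Median centring left cholesterol at 0.0612, and quantile normalization cell cycle at 0.263. Among genes at or above the median intensity, 281 genes were at 1.5-fold (107 higher, 174 lower) and 4 lists were called, with TGF-β response at 0.988 in the other direction, cell cycle at 0.251, interferon, stress response and p53 at 0.281 and hypoxia at 0.192. Above the 25th percentile 4 lists were called, with cell cycle, stress response, cholesterol, p53 and cholangiocyte markers at 0.0643, hypoxia at 0.0507 and macrophage markers at 0.692 in the other direction. Over all probe sets 1156 were at 1.5-fold (581 higher, 575 lower) and 6 lists were called, with cell cycle and p53 at 0.0581, stress response at 0.0579 and cholangiocyte markers at 0.0576. With an estimated correlation 0 lists were called: matrix, cholesterol and cholangiocyte markers at 0.566, EGFR/MAPK at 0.253, cell cycle and interferon at 0.630, stress response, p53 and hypoxia at 0.608, and NF-kB at 0.121. Fry called 5, with cell cycle at 0.0954, interferon at 0.0721, stress response at 0.0768, and hypoxia and cholangiocyte markers at 0.0551. Beyond the smaller sets tested, the cause was not tested.

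With the replicate block 2115 genes and 6 lists were called, with matrix, cell cycle, cholesterol and p53 at 0.05002. Deviations of same-numbered samples correlated at -0.08, 0.16 and 0.09, and not every sample correlated best with its own number. The seed-site test was not run. Signal over background is unknown and limits what can be said of dim genes.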

Other observations

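The tests and sets of this part were chosen after the data were seen. Several genes outside the lists rose with antimiR-214. Probe sets named for the microRNA genes MIR221 and MIR222, which do not tell precursor from primary transcript here, were 2.25-fold and 2.11-fold higher (adjusted p = 0.000448 and 0.00438), and MIR17HG, the host of the miR-17 cluster, was 1.85-fold higher (adjusted p = 0.00139). As a family, 179 MIR symbols were not called (adjusted p = 0.829), with 7 higher and 4 lower. The plasminogen activators PLAU and PLAT were 2.12-fold and 1.70-fold higher, the hyaluronan synthase HAS2 2.07-fold, the transglutaminase TGM2 2.35-fold, the long non-coding RNA UCA1 2.33-fold and the endotoxin receptor TLR4 2.28-fold. Of 44 collagen (COL) genes, 6 fell, none rose and only 6 were above 0, but the family was not called (adjusted p = 0.0644).

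Families were formed by the letters that start a symbol, with 10 or more measured members, and camera called 12 of 247, 11 higher and 1 lower, and 0 with an estimated correlation. The higher families were POLR, MRPL, RPL, EIF, SNORA, RPS, DUSP, SNORD, SF, MRPS and MT. The lower family was CHD, of chromatin remodellers, where CHD2 was 1.82-fold lower. Other families of RNA-processing genes were not called, among them EXOSC (adjusted p = 0.181), LSM (0.188), DDX (0.288), RBM (0.293), PRPF (0.329), SRSF (0.834) and DHX (0.975). Of 48 MRPL genes, 8 rose and none fell, with a mean difference of 0.16 log2 units, and of 31 POLR genes, 7 rose and 1 fell, with a mean of 0.18. Of 115 SNORD genes, 25 rose and 1 fell, with a mean of 0.13, but antimiR-214 replicate 3 lay at -0.02 against 0.20 and 0.22 for replicates 1 and 2. Of 61 SNORA genes, 10 rose and none fell, with a mean of 0.18, and replicate 3 lay at 0.03 against 0.21 and 0.29.

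Cytosolic ribosomal protein genes (RPL and RPS, 96 symbols, some of them pseudogenes or related genes) differed by a mean of 0.15 log2 units, with 79 above 0, 19 past the threshold higher and 3 lower. Their mean on antimiR-214 replicate 3 was 0.089 above the control mean, against 0.16 and 0.20 on replicates 1 and 2. A brightness offset is argued against by percentile 100 among brightness-matched random lists, and a single array by the highest camera p with 1 array left out, 2.69e-06. An axis unrelated to the groups is argued against for these genes, as no split of the group-centred arrays gave a difference above 0.052. For the SNORD family that difference was 0.14, as large as the one between the groups. It was 0.11 for SNORA and 0.081 for MT, where the groups differed by 0.18 and 0.16, so such an axis stays open for these 3 families. It stays open for the interferon list too, with 0.14 against a difference of 0.22 between the groups. Gene length, a batch that coincides with the groups and an effect of the inhibitor's sequence were not tested. With an estimated correlation the ribosomal set had a camera p of 0.119. For these reasons a shift in ribosome production may be named only as a hypothesis.

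The count of families is not specific to the groups. As many families or more were called in 3 of the 10 splits, the real one included. The split that sets antimiR-214 replicates 1 and 2 and control replicate 2 against the rest called 46, which points to a structure of the samples. On the second principal component (18.0% of variance, after 52.8% for the first) antimiR-214 replicate 3 lay at -17.9, where the other arrays lay between -4.20 and 8.90, and its array weight was 0.600.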
